A study of Mus musculus with 18 samples.

How the data were processed

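RNA was measured in 18 libraries of mouse bone marrow cells, 3 in each of 6 groups. The cells were CD45.2-positive iLS cells of C57BL/6 mice, sorted by flow cytometry. Per the labels' protocols, RNA was isolated on columns and poly(A)-selected, and libraries were made with a kit that keeps the strand of the RNA. The groups were control cells, cells with BRD9-NUTM1 (BN1) and cells with AFF1-NUTM1 (AFFN1), each on day 6 and on day 14. The sample descriptions follow a different naming scheme on each day, so the days may belong to separate experiments, and a difference between the days cannot be told apart from a difference between experiments.

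The deposited table holds expected counts of reads per gene, which need not be whole. STAR, RSEM and DESeq2 were used and mm10 was the genome build, per the submitters' processing notes. Their versions, the gene annotation and the strand setting of the counting are not given in the sources used here. Between 1.74 and 2.12% of the values in a library were not whole, and the expected counts were rounded to whole numbers before any test. The table has 32285 genes, of which 78 share their name with another gene and were kept apart by gene identifier. Of all gene identifiers, 32158 (99.6%) were found in the GENCODE M21 annotation of mm10, from which the coordinates were taken.

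All tests were done in R 4.3.3. Genes with low counts were removed with the filterByExpr function of edgeR 4.0.16, libraries were scaled by TMM, and groups were compared with edgeR's quasi-likelihood test with robust estimation. The p-values were two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Comparisons within a day were fitted on the 9 libraries of that day. Comparisons across days, including the difference between a fusion's effects on the 2 days, were fitted on all 18. Counts per 1e6 counts (CPM) are scaled by TMM within the libraries of the fit. In total, 9 comparisons were made. Gene lists were tested with limma's camera (limma 3.58.1) at a preset correlation between genes of 0.01, for the lists with at least 3 tested genes, and again with the correlation estimated from the data. The 25 lists hold 386 genes, of which 2 are absent from the table. Of all list calls at the preset correlation, those of the sex-linked genes between days and of the Hoxa cluster in the change of the AFFN1 effect between days also passed with an estimated correlation, and no other did. With the block the Hoxa cluster no longer passed with an estimated correlation (adjusted p = 0.0591).

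The groups, comparisons, lists, tests and the rule for the genes to be named were chosen before the data were examined. The rule took the 10 called genes with the largest rise and the 10 with the largest fall in each comparison of a fusion with control, and 5 each in the other comparisons. These genes needed a mean of at least 5 CPM in the higher group and groups that did not overlap. It also took 13 fixed genes (Nutm1, Brd9, Aff1, Hoxa9, Hoxa10, Meis1, Ebf1, Pax5, Il7r, Kit, Flt3, Myc and 1 gene that is not reported here) and up to 4 called members of each called list. Genes with the smaller changes may be left out of the text. For the change of an effect between days the groups cannot be compared for overlap, and the CPM minimum was applied to the highest of the 4 groups. For day 14 the rule was also applied to the fit with the replicate number, with the same direction in each of the 3 numbered pairs in place of separate groups. That application was chosen after seeing the data.

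The labels number the replicates 1 to 3 in each group. Whether equal numbers pair the libraries was checked from the correlation of the libraries' deviations from their group means, before calls were compared. On day 14 all 9 pairs of libraries with the same number correlated at 0.29 to 0.612, and the 18 pairs with different numbers at -0.503 to 0.0122, and the descriptions give libraries of the same number in the 3 groups the same code. The numbers were therefore taken as pairs on day 14, and results with the replicate number as a block are given beside the others where they differ. On day 6 the numbers did not pair the libraries of all 3 groups. Control and BN1 libraries of the same number correlated at 0.157, 0.338 and 0.349, and those of different numbers at -0.358 to 0.0774. AFFN1 libraries correlated with control and BN1 libraries of the same number at -0.322 to 0.222, and with those of other numbers at up to 0.398. The numbers were therefore not taken as pairs on day 6.

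The labels do not say that the replicates came from separate cultures or animals. The p-values therefore measure only the spread between these samples, which may be technical. No library was within counting noise of another library of its group, so none was treated as a duplicate. The day 6 libraries AFFN1 1 and AFFN1 2 were the closest. The chi-square per degree of freedom between their counts was 3.97, against 11.6 to 131 for the other pairs within groups. Total counts per library, in 1e6, were 14.2 to 18.4. A gene with 0 reads in a library lies under a floor of 3 counts, or 0.163 to 0.212 CPM. A fold change against a group with 0 reads is given as a lower bound computed against 3 counts over that group. With 1 to 3 reads in a group, the ratio is given with its 95% counting interval. Floors and intervals cover counting error only. The table gives no way to separate reads shared by near-identical genes or by genes that overlap on opposite strands.

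The tests were checked on simulated counts with 200 genes changed by 1.5-, 2- and 4-fold. For BN1 against control on day 6, 37.3%, 70.1% and 90.9% of these genes were recovered, and for AFFN1 against control on day 6, 41.8%, 64.2% and 93.9%. For BN1 on day 14 the shares were 7.46%, 47.8% and 81.8%, and with the block 22.4%, 73.1% and 81.8%. For AFFN1 on day 14 they were 2.99%, 29.9% and 86.4%, and with the block 19.4%, 71.6% and 86.4%. With the block the share of false calls on day 14 went from 5.21 to 10.6% of the calls for BN1 and from 8.14 to 10.6% for AFFN1, above the 5% aimed at. Between the fusions on day 14 it was 6.74% without and 6.35% with the block. Each share comes from a single simulated set. Alternatives tried were DESeq2 1.42.0, scaling by relative log expression, no filter on low counts, all 18 libraries in one fit, a fit on the 6 libraries compared, the replicate block, an estimated correlation in the list tests, and leaving out each library in turn. For comparisons that share the control libraries, 100 sets of unchanged groups were simulated for each fit. Almost no genes were called in these sets, so their overlap gives no baseline for long lists of calls.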

Results

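Gene expression was measured in iLS cells sorted from mouse bone marrow, in a series about leukemia with rearranged NUTM1, a gene normally active in the testis. The cells were control cells or carried a fusion of NUTM1 with BRD9, a subunit of a chromatin remodelling complex (BN1), or with AFF1, a transcription elongation factor (AFFN1). Each kind was profiled on day 6 and on day 14, with 3 libraries per group. Total counts, in 1e6, were 16 ± 1.76, 16 ± 0.864 and 15.9 ± 0.812 (SD, n = 3) for control, BN1 and AFFN1 on day 6, and 18.2 ± 0.215, 18 ± 0.162 and 18.2 ± 0.156 on day 14. Libraries of the days were apart on the first principal component, which held 52.6% of the variance. The control and AFFN1 libraries numbered 1 of day 14 were apart from the other day 14 libraries on the second, which held 11.7%. Mouse Nutm1 had 0 to 2 reads over the 3 libraries of any group, and the labels do not say from which species the NUTM1 part of the fusions came.

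**Figure D1:**
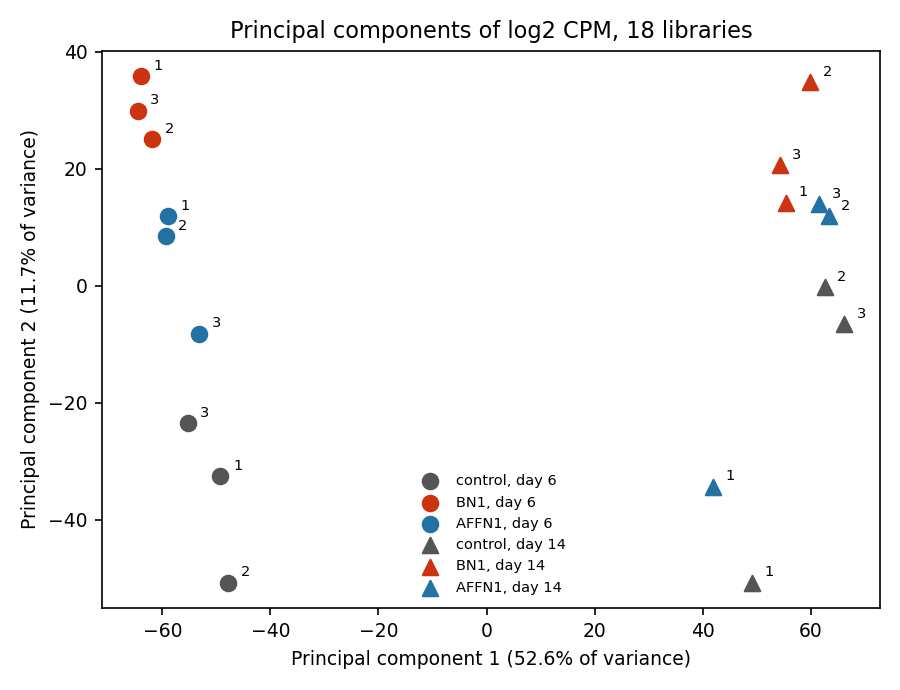
Positions of the 18 libraries on the first and second principal components of log2 CPM. Each point is 1 library, with the kind of cell shown by colour, the day by the shape of the point and the replicate number beside it. Day 6 and day 14 libraries are apart on the first component (52.6% of the variance).

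Which transcripts differ between BN1 and control cells was asked first on day 6. BN1 cells had far higher levels of several transcripts that were near the detection floor in control cells. Gnb4 (ENSMUSG00000027669; mm10 chromosome 3, 32580332 to 32616585), which encodes a G protein beta subunit, was 490-fold higher, at 55.7 ± 3.35 against 0.0988 ± 0.0882 CPM (SD, n = 3; log2 fold change 8.94, SE 0.29, adjusted p = 7.15e-08). Lin28b, an RNA-binding protein of fetal progenitors, was 93.1-fold higher, at 20.4 ± 1.32 against 0.21 ± 0.0786 CPM (adjusted p = 3.01e-07). Hoxa9 (ENSMUSG00000038227; mm10 chromosome 6, 52223100 to 52231089), a homeobox transcription factor of early progenitors, was 50.5-fold higher, at 14.3 ± 5.25 against 0.27 ± 0.117 CPM (log2 fold change 5.66, SE 0.40, adjusted p = 1.31e-05). Acsf2, an acyl-CoA synthetase, rose 47.3-fold, from 1.99 ± 0.33 to 95.4 ± 5.75 CPM. Scube3, Tnik, Kctd17, Klhl22, Ctbs and Pafah1b3 rose between 42.3- and 53.9-fold, with adjusted p of 0.000318 or lower.

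Other transcripts were nearly lost in BN1 cells on day 6. Zfp267 (ENSMUSG00000033883; mm10 chromosome 3, 36151017 to 36170342), a zinc finger gene, had 0 reads in BN1 and 11.1 ± 1.5 CPM (SD, n = 3) in control, at least 181-fold lower (adjusted p = 6.07e-06). Mdfi, an inhibitor of myogenic transcription factors, also had 0 reads and was at least 89.4-fold lower. Eci2, an enzyme of fatty acid oxidation, was 285-fold lower, at 0.0831 ± 0.0385 against 25.7 ± 2.1 CPM (adjusted p = 1.36e-08). For Rps6kc1, with 1 read in BN1, the ratio of control to BN1 was 327 (95% counting interval 58.3 to 13000), and for Nxt2, with 3 reads, it was 133 (45.1 to 647). Itm2a and Cntln were 107- and 80.4-fold lower. Of the fixed genes, Meis1, a cofactor of Hox proteins, rose from 3.19 ± 1.13 to 17.4 ± 5.13 CPM (log2 fold change 2.46, adjusted p = 0.000285). Flt3, a receptor tyrosine kinase of early progenitors, rose from 37.1 ± 3.62 to 85.8 ± 12.5 CPM (log2 fold change 1.21, adjusted p = 0.00072), and Pax5, a B-lineage transcription factor, rose 1.41-fold (adjusted p = 0.00703). Hoxa10 was too low for the test, with 16 reads in BN1 and 2 in control (ratio 7.75, interval 1.82 to 69.5). Ebf1, Il7r, Kit, Myc, Brd9 and Aff1 were not called, with log2 fold changes of 0.35, 0.39, -0.43, -0.10, -0.03 and 0.31.

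In all, 2095 of 12068 tested genes were called by edgeR between BN1 and control on day 6, 1066 higher and 1029 lower, and 824 of them by more than 2-fold. Of the 5 tested genes of the Hoxa cluster, which is active in stem cells and early progenitors, 3 rose and none fell (4 rose adjusted over the list alone), with a median log2 fold change of 3.97. Besides Hoxa9 these were Hoxa7, 15.7-fold higher, and Hoxa5, with 66 reads in BN1 and 1 in control (ratio 63.9, interval 11.1 to 2560). The list's adjusted p was 3.24e-06 by camera, and the adjusted p = 0.403 with an estimated correlation. The list has 11 members, and those not tested had too few reads. The list's median was 0.0994 to 0.337 CPM in the control libraries, so most tested members likely passed the filter through the fusion groups. This tilts the share that rose and the median towards a rise. Without the filter 0 of the 3 list calls of this comparison were lost. Of 15 erythroid and megakaryocyte genes 4 passed the filter, and 2 of these rose, over all genes and adjusted over the list alone. Car2, a carbonic anhydrase, rose 31.2-fold to 28.6 ± 0.735 CPM (SD, n = 3), and the beta globin gene Hbb-bt 2.56-fold to 4.01 ± 0.604 CPM. This list had an adjusted p of 8.18e-05, and an adjusted p = 0.0857 with an estimated correlation. Of 18 interferon response genes 5 rose and none fell (12 rose adjusted over the list alone; median log2 fold change 0.48, adjusted p = 0.00112, and adjusted p = 0.745 with an estimated correlation). Ifit1 rose 1.86-fold, Usp18 1.85-fold and Zbp1, a sensor of nucleic acids, 2.1-fold, the last with adjusted p of 0.0587 without control 1 and 0.0592 without BN1 1. The list's median CPM was 34.3, 38.4 and 54.9 in the control libraries and 55.9, 71.4 and 62.1 in BN1. Of the 20 genes of pro-B and pre-B cells, 7 rose and none fell, and of 17 B-lineage transcription factors 7 rose and 1 fell, but neither list passed its test (adjusted p = 0.0538 for both). Of 12 later B-cell genes 6 rose and 2 fell, and this list did not pass either (median log2 fold change 0.435, adjusted p = 0.13 by camera). Immediate early and stress genes were high in the libraries numbered 3 of control and BN1, with a median of 54 and 77.8 CPM against 10.7 to 31.2 in the other day 6 libraries. The number of calls was 1246, 1360, 3495 and 1141 without control 1, control 2, control 3 and BN1 1, and 3890 without the 3 libraries numbered 3. Groups did not overlap in 33.9% of the tested genes, where chance gives 10%.

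The same question was asked of AFFN1 on day 6. In AFFN1 cells, as in BN1 cells, Hoxa9, Meis1, Flt3 and Gnb4 rose against control. Ttc30a1 (ENSMUSG00000075271; mm10 chromosome 2, 75978247 to 75981967), a gene of transport within cilia, had 7.71 ± 1.74 CPM (SD, n = 3) against 0 reads in control, at least 121-fold higher (adjusted p = 0.000997). Crip1 (ENSMUSG00000006360; mm10 chromosome 12, 113146316 to 113153879), a LIM domain gene, was 202-fold higher, at 22.9 ± 3.31 against 0.0999 ± 0.115 CPM (log2 fold change 7.66, SE 0.46, adjusted p = 1.04e-05). Gnb4 was 91.9-fold higher at 10.4 ± 1.59 CPM, and Hoxa9 58.8-fold higher at 16.6 ± 2.41 CPM (adjusted p = 2.73e-05). Ly6c2, a surface antigen of monocytes, rose from 7.77 ± 1.79 to 239 ± 53.7 CPM (log2 fold change 4.94, adjusted p = 0.000267). Zfp518b, Ajuba, Islr, Cldn34c1 and Gtf2ird1 rose between 17.9- and 27.3-fold. Among the lower genes, Fetub fell from 22 ± 2.01 to 0.766 ± 0.887 CPM, by 4.83 on the log2 scale (adjusted p = 0.00272), and Ccdc125 from 10.6 ± 3.7 to 0.455 ± 0.3 CPM. Als2cl was 19.4-fold lower (adjusted p = 0.00986; 0.0613 without AFFN1 1 and 0.0608 without AFFN1 2). Ppp1r9a and the fibronectin receptor subunit Itga5 were 18.7- and 17.5-fold lower.

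Meis1 rose to 20.8 ± 2.21 CPM (SD, n = 3) in AFFN1 on day 6, a log2 fold change of 2.71 (adjusted p = 0.000303), and Flt3 to 133 ± 27.2 CPM, a log2 fold change of 1.84 (adjusted p = 0.000105). Pax5 rose 1.29-fold (adjusted p = 0.0363). That call ended without AFFN1 1, AFFN1 2, control 1 or control 2, with adjusted p of 0.144, 0.121, 0.0624 and 0.0696. Hoxa10, untested, had 13 reads in AFFN1 and 2 in control (ratio 6.38, interval 1.44 to 58.2). Ebf1, Il7r, Kit, Myc, Brd9 and Aff1 had log2 fold changes of -0.10, 0.02, -0.09, -0.49, -0.11 and 0.28 and were not called. In all, edgeR called 1528 genes, 940 higher and 588 lower, and 706 of them by more than 2-fold. The number was 739 without AFFN1 1 and 747 without AFFN1 2, and 3873 without the 3 libraries numbered 3. Groups did not overlap in 32.3% of genes, against 10% by chance.

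Of 11 Hoxa genes 5 passed the filter, and all 5 rose in AFFN1 on day 6, also when adjusted over the list alone (median log2 fold change 4.11, adjusted p = 5.69e-13, and adjusted p = 0.169 with an estimated correlation). As for BN1, the filter tilts these values towards a rise. Without it 1 of the 6 list calls of this comparison was lost. Hoxa7 was 17.1-fold higher and Hoxa5 had 88 reads against 1 (ratio 86.4, interval 15.1 to 3450). Of 12 later B-cell genes 5 rose and none fell (7 rose adjusted over the list alone; adjusted p = 0.00109, and adjusted p = 0.221 with an estimated correlation). Among them Cd22, an inhibitory receptor of B cells, rose 5.56-fold to 118 ± 6.2 CPM (SD, n = 3). The later B-cell list did not pass between BN1 and AFFN1, with 2 genes higher and 4 lower in BN1 (adjusted p = 0.265 by camera). In AFFN1 against control, 6 of 17 B-lineage transcription factors rose and 3 fell. Of 20 pro-B and pre-B genes 4 rose and 2 fell, and neither list passed by camera (adjusted p = 0.518 and 0.437). Of 6 dendritic cell genes 2 rose, the chemokine receptor genes Ccr9, 7.82-fold to 305 ± 53.5 CPM, and Ccr7, 3.42-fold (4 rose and 1 fell adjusted over the list alone; adjusted p = 0.000115, and adjusted p = 0.221 with an estimated correlation). Of 15 erythroid and megakaryocyte genes 4 passed the filter. Of these 2 rose, also when adjusted over the list alone, and Car2 rose 3.4-fold. This list had an adjusted p of 0.0415, and an adjusted p = 0.239 with an estimated correlation. Its call ended without control 1, control 2, control 3, AFFN1 1 or AFFN1 3, with adjusted p of 0.118, 0.165, 0.0646, 0.131 and 0.0746. Of 18 interferon response genes 6 rose and none fell (9 rose adjusted over the list alone; median log2 fold change 0.63, adjusted p = 3.84e-06, and adjusted p = 0.741 with an estimated correlation). Zbp1 rose 3.33-fold, and Usp18 1.78-fold, while the list's median was 67.7, 65.5 and 56.6 CPM in the AFFN1 libraries. Of 20 Myc and ribosome biogenesis genes 1 fell over all genes and none when adjusted over the list alone, with a median log2 fold change of -0.46 (adjusted p = 0.00108, and adjusted p = 0.844 with an estimated correlation; 0.0576 without control 2). The list's median was 93.8 and 92.8 CPM in AFFN1 1 and AFFN1 2 but 158 CPM in AFFN1 3, against 148, 198 and 127 CPM in the control libraries.

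**Figure D2:**
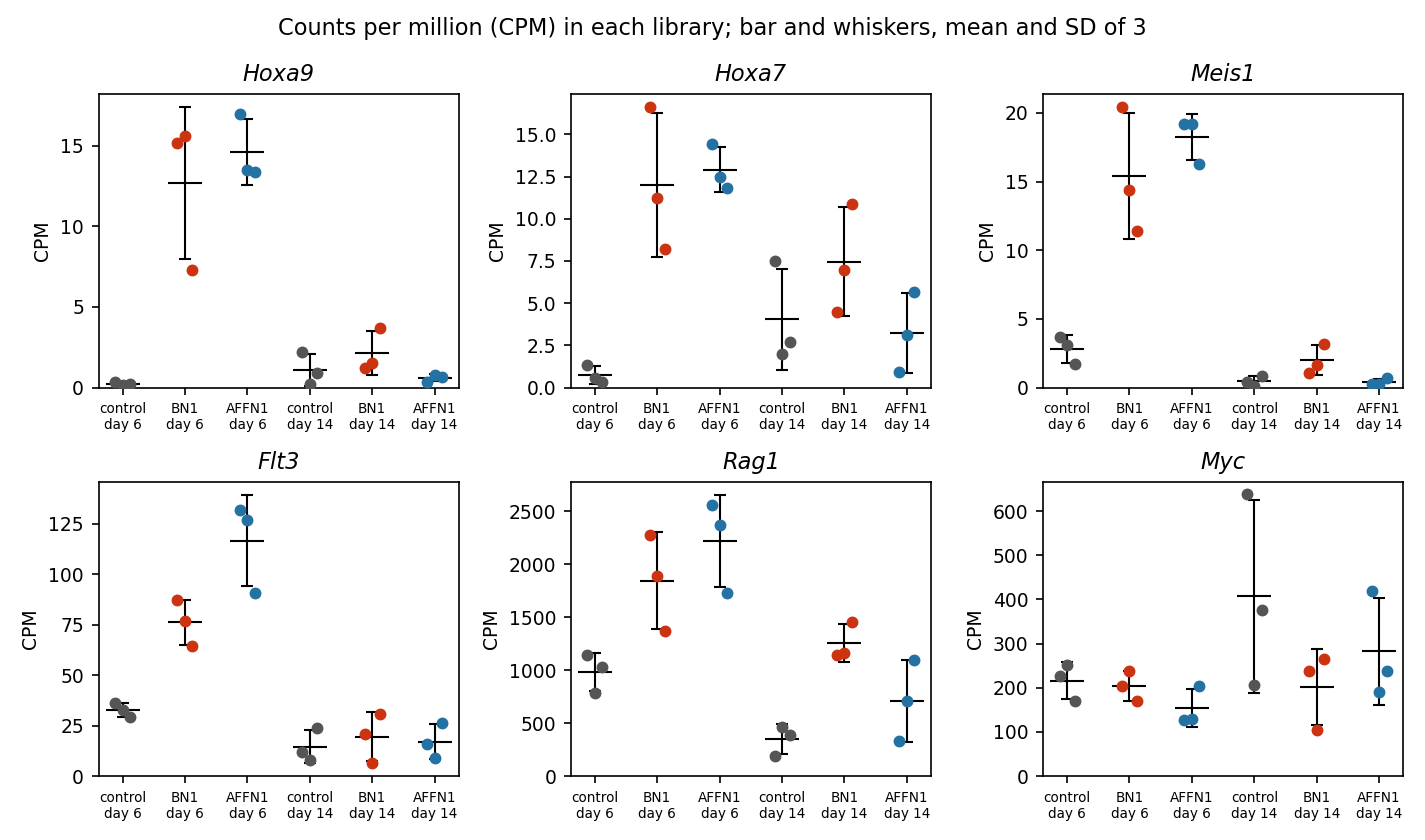
CPM of Hoxa9, Hoxa7, Meis1, Flt3, Rag1 and Myc in each library, scaled over all 18 libraries, by group and day. Points are libraries, and bars are the mean ± SD of 3. Hoxa9 was 13.4 CPM or higher in 5 of the 6 fusion libraries of day 6 and 7.28 CPM in the sixth, BN1 3, and 0.337 CPM or lower in the day 6 controls.

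The calls of both fusions on day 6 overlapped. In all, 480 genes rose in both and 254 fell in both, where independent lists would share 83 and 50.1, and 48 were called in opposite directions. Both comparisons use the same control libraries. With unchanged groups simulated against such controls, the mean overlap was 0 genes higher and 0.01 lower over 100 simulations. A mean of only 0.18 genes for BN1 and 0.2 for AFFN1 was called in them. So few calls could not overlap, and these simulations cannot say how much of the overlap comes from the shared controls. The log2 fold changes of both comparisons correlated across genes at 0.535 (0.5 in the simulations), and genes are not independent replicates. Their covariance was 0.345, against 0.0339 in the simulations. With 3 controls these could not be split into sets of 2 or more, so part of the excess may come from the shared controls.

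Whether the fusions differ from each other was tested directly. On day 6 BN1 cells had more Klk8 (ENSMUSG00000064023; mm10 chromosome 7, 43797577 to 43803826), a kallikrein-related protease gene, with 8.79 ± 0.783 CPM (SD, n = 3) and 2 reads in AFFN1 (ratio 210, interval 57.9 to 1740; adjusted p = 3.08e-05). Acsf2 was 51.7-fold higher in BN1 than in AFFN1 (adjusted p = 2.28e-08), Tmem132e 57.2-fold, Myom2 36.9-fold and Ydjc 18.1-fold. AFFN1 cells had more Ccdc166, with 1 read in BN1 (ratio 392, interval 69.9 to 15500), more Crip1 by 255-fold, Eci2 by 218-fold and Itm2a by 87.5-fold, and more Nxt2, with 3 reads in BN1 (ratio 93.9, interval 31.8 to 458). Flt3 was lower in BN1, with a log2 fold change of -0.63 (adjusted p = 0.0291; 0.11, 0.114, 0.0815 and 0.104 without AFFN1 1, AFFN1 2, BN1 2 and BN1 3). Hoxa9 and Meis1 were not called between the fusions, with log2 fold changes of -0.22 (SE 0.26, adjusted p = 0.656) and -0.26 (SE 0.25, adjusted p = 0.573). In all, edgeR called 1349 of 12068 genes, 602 higher in BN1 and 747 lower, and 787 without AFFN1 1 and 725 without AFFN1 2. Groups did not overlap in 35% of genes, against 10% by chance.

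Between the fusions on day 6, 2 of 4 erythroid and megakaryocyte genes were higher in BN1 and 1 was lower, also when adjusted over the list alone (adjusted p = 0.0222, and adjusted p = 0.432 with an estimated correlation). Car2 was 9.19-fold higher (adjusted p = 1.01e-05). Of 6 dendritic cell genes 2 were lower in BN1 (4 adjusted over the list alone; adjusted p = 0.0383, and adjusted p = 0.874 with an estimated correlation). Bst2, which restricts virus release and is induced by interferon, was 81.4 ± 5.94 CPM in BN1 and 196 ± 22.3 CPM in AFFN1 (SD, n = 3). The dendritic list was not called without AFFN1 1 (adjusted p = 0.0557), AFFN1 2 (0.0668), BN1 1 (0.0608) or BN1 3 (0.0579). Of 17 stromal cell genes 2 were lower in BN1, also when adjusted over the list alone, with a median log2 fold change of -1.34 (adjusted p = 0.0222, and adjusted p = 0.874 with an estimated correlation). This call ended without AFFN1 2 (adjusted p = 0.166), BN1 1 (0.0528) or BN1 2 (0.0745). The library AFFN1 2 had the highest median of stromal genes, 4.75 CPM, with Col1a1 at 15.6 CPM and Fn1 at 55.3 CPM, while the other 8 day 6 libraries had medians of 0.489 to 2.81 CPM.

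On day 14 the comparison of BN1 with control found few genes without the replicate pairs and many with them. Gldc (ENSMUSG00000024827; mm10 chromosome 19, 30098447 to 30175429), which breaks down glycine, fell by 5.68 on the log2 scale, from 24.4 ± 9.06 to 0.469 ± 0.312 CPM (SD, n = 3; adjusted p = 0.0114; 0.0511 without BN1 1). Ccl9 (ENSMUSG00000019122; mm10 chromosome 11, 83572919 to 83578636), a chemokine gene, rose from 14.5 ± 5.77 to 91.4 ± 14.4 CPM (log2 fold change 2.65, SE 0.28, adjusted p = 0.0215; 0.0569, 0.0677 and 0.0933 without control 2, BN1 1 and BN1 2). Sh2d5 rose 2.39-fold (adjusted p = 0.028; 0.083, 0.0933, 0.0635, 0.0569 and 0.192 without BN1 1, BN1 2, control 1, control 2 and control 3). These 3 were the edgeR calls among 11657 genes, with 2351 at an unadjusted p under 0.05, and DESeq2 called 642. With scaling by relative log expression edgeR called 5, 4 higher and 1 lower, against 2 and 1. The number was 5, 1, 1 and 1 without control 1, control 2, BN1 1 and BN1 2. With the replicate number as a block, 1348 genes were called, 577 higher and 771 lower, and 594, 143 and 684 without the libraries numbered 1, 2 and 3. In 28.1% of genes the groups did not overlap, against 10% by chance for unpaired libraries.

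With the replicate block, Zfp709, Pcp4l1, Cysltr1, Tmtc1 and Eya1 rose in BN1 on day 14 by 3.45 to 4.14 on the log2 scale, and Smoc1, Slc15a2, Bace1 and Maf by 2.79 to 3.39. Without the block these 9 genes had adjusted p between 0.0502 and 0.128. The largest fall was that of Ccnd1, the cyclin D1 gene, from 156 ± 109 to 1.06 ± 0.0643 CPM (SD, n = 3; log2 fold change -6.96 with the block, adjusted p = 0.0222; 0.0828 without it). Gldc, which was also called without the block, followed with -5.73, then Armcx3 with -5.61, Sdc3 with -3.90, the immune checkpoint receptor gene Pdcd1 with -3.50, the cytokine gene Lif with -3.48 and Plxna2 with -2.98. Of the fixed genes, Kit (1.03), Meis1 (2.11) and Il7r, the receptor of interleukin 7 (0.91), rose on the log2 scale with the block, with adjusted p of 0.0185, 0.0284 and 0.0284. Without it their adjusted p was 0.109, 0.161 and 0.191. Meis1 was low, at 1.75 ± 0.959 against 0.421 ± 0.337 CPM. Myc fell by 0.95 with the block (adjusted p = 0.0231; 0.302 without). Hoxa9 was 1.9 ± 1.19 against 0.978 ± 0.881 CPM and was not called (adjusted p = 0.486; 0.393 with the block). Brd9, Aff1, Ebf1, Pax5 and Flt3 were not called with or without the block, with log2 fold changes of 0.13, 0.35, 0.36, 0.38 and 0.41. Hoxa10 had 0 reads.

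Some lists of growth genes were lower and some lists of B-lineage genes higher in BN1 on day 14 by camera, none of them with an estimated correlation. Mitosis genes (20 tested, none called; adjusted p = 0.583) and later B-cell genes (16 tested, 1 lower with the block; median log2 fold change 0.13, adjusted p = 0.593) did not pass. Neither did T, NK and innate lymphoid genes (adjusted p = 0.242), though 4 of 12 were higher and 1 lower with the block (4 and 2 adjusted over the list alone), so single genes of other lineages rose too. No list member was called without the block, and the numbers of members given for day 14 are with the block unless stated. The lists' adjusted p by camera and median log2 fold changes are from the fit without the block unless stated. With the block 1 of the 10 list calls was lost, that of the interferon response list. Some others were weaker by camera, with adjusted p of 0.0102 for KMT2A-fusion targets and 0.0407 for stromal cell genes. Of 20 Myc and ribosome biogenesis genes 17 fell and none rose (20 fell adjusted over the list alone, and 19 without the block). Their median log2 fold change was -0.87 (adjusted p = 5.23e-15, and adjusted p = 0.295 with an estimated correlation). Srm, which makes spermidine, fell by 1.35, Ldha by 1.13, Odc1 by 1.09 and Gnl3 by 1.01 on the log2 scale. Of 20 DNA replication genes 6 fell and none rose (11 fell adjusted over the list alone; adjusted p = 7.77e-06, and adjusted p = 0.448 with an estimated correlation), among them Ccne1 by 0.64 and Ung by 0.63. Of 15 p53 target genes 5 fell and 1 rose (10 fell and 1 rose adjusted over the list alone; adjusted p = 0.000349, and adjusted p = 0.181 with an estimated correlation). Phlda3 fell by 1.44, Aen by 1.06, the pro-apoptotic gene Bax by 0.88 and the cell cycle inhibitor Cdkn1a by 0.73.

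Of 20 pro-B and pre-B genes 5 rose in BN1 on day 14 and none fell (8 rose adjusted over the list alone; adjusted p = 0.000349, and adjusted p = 0.532 with an estimated correlation). Rag1, which cuts DNA for antigen receptor recombination, rose from 307 ± 124 to 1110 ± 152 CPM (SD, n = 3; log2 fold change 1.97, SE 0.29, adjusted p = 0.0137 with the block and 0.114 without), its partner Rag2 by 1.35 and Blnk by 0.76. Of 17 B-lineage transcription factors 5 rose and none fell (8 rose adjusted over the list alone; adjusted p = 0.00188, and adjusted p = 0.295 with an estimated correlation), among them Foxo1 by 0.73 and Lef1 by 0.72. Of 15 targets of KMT2A fusions 4 rose, among them Meis1 and Eya1, and 1 fell (5 rose and 1 fell adjusted over the list alone; adjusted p = 0.00265, and adjusted p = 0.181 with an estimated correlation). Of 13 stem and multipotent progenitor genes 3 rose, Meis1, Kit and Erg (4 adjusted over the list alone; adjusted p = 0.0265, and adjusted p = 0.311 with an estimated correlation). That list's call ended without BN1 1 (0.0519), control 2 (0.213) or control 3 (0.0554). Of 16 immediate early and stress genes 2 rose, Jun by 1.01 and Btg2 by 0.98, also when adjusted over the list alone (adjusted p = 0.0137, and adjusted p = 0.452 with an estimated correlation). Of 14 stromal cell genes 1 fell, Fbn1 by 2.04, also when adjusted over the list alone (adjusted p = 0.0159, and adjusted p = 0.532 with an estimated correlation; 0.132 without BN1 2 and 0.103 without control 3). The erythroid and megakaryocyte list passed with the block alone (2 of 3 genes fell, Hbb-bt by 1.59; adjusted p = 0.0176 with the block, adjusted p = 0.215 with the block and an estimated correlation, and 0.223 without the block). No member of the interferon response list was called in 15 tested genes, over all genes or adjusted over the list alone, with or without the block. The list's median log2 fold change was -3.34 (adjusted p = 0.03 by camera, and adjusted p = 0.694 with an estimated correlation; 0.0847 with the block). It was not called without control 1 (adjusted p = 0.778) or BN1 3 (0.0512). Its median CPM was 59.8 in control 1 and 65.2 in AFFN1 1, against 0.759 to 1.57 in the other 7 libraries of day 14.

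**Figure D3:**
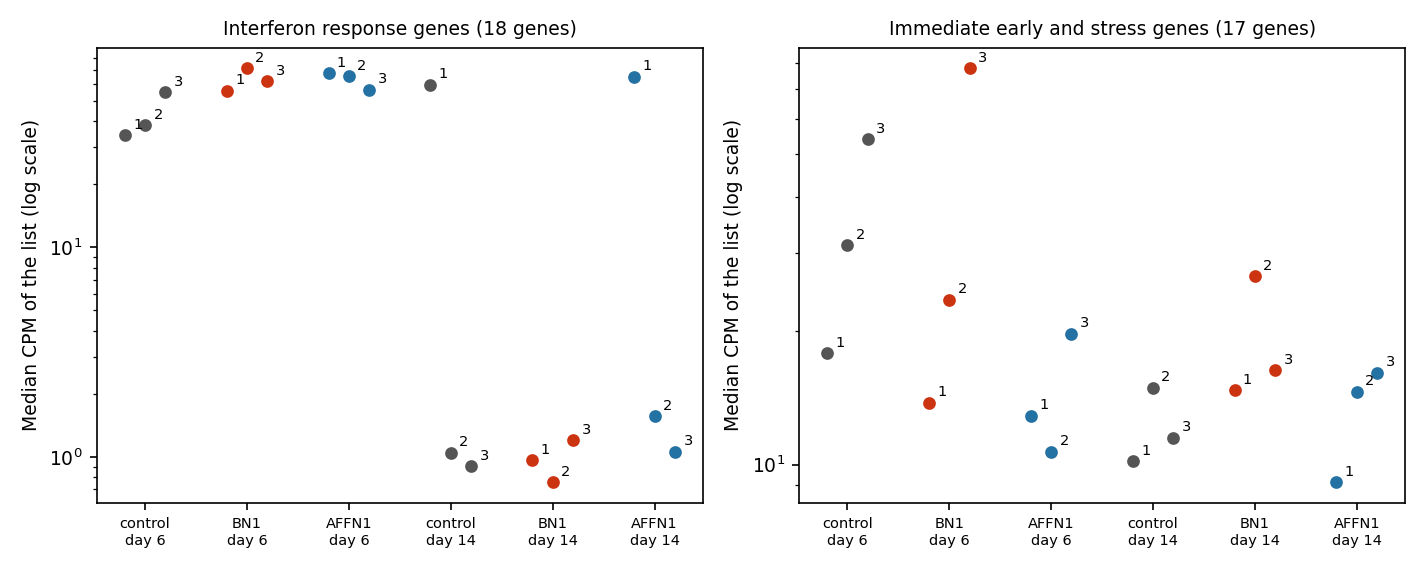
Median CPM of 18 interferon response genes and of 17 immediate early and stress genes in each of the 18 libraries, on log axes. Interferon response genes were at 59.8 and 65.2 CPM in control 1 and AFFN1 1 of day 14 and between 0.759 and 1.57 CPM in the other 7 libraries of that day.

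Few genes were called between AFFN1 and control cells on day 14. Smaller differences may have been missed, as 29.9% of simulated 2-fold changes were recovered without the block. Gldc fell here too, from 24.4 ± 9.06 to 0.0919 ± 0.0276 CPM (SD, n = 3; log2 fold change -7.93, SE 0.63, adjusted p = 0.00302; 0.0815 without AFFN1 3). Bace1, the beta-secretase gene, rose from 0.924 ± 0.416 to 8.73 ± 1.23 CPM and Ppp1r32 from 1.5 ± 0.324 to 8.02 ± 1.8 CPM, and B4galt4 fell from 15.1 ± 4.27 to 4.75 ± 0.339 CPM (adjusted p = 0.0432 for each). The call of Bace1 ended without AFFN1 1, AFFN1 2, AFFN1 3, control 2 or control 3 (0.0788, 0.0522, 0.213, 0.156 and 0.13). That of Ppp1r32 ended without AFFN1 2, AFFN1 3, control 2 or control 3 (0.0522, 0.213, 0.156 and 0.216), and that of B4galt4 without any 1 of the 6 libraries (0.0646 to 0.221). The fifth call, Bmpr1a, a receptor of bone morphogenetic proteins, lay outside the rule for named genes and was chosen after its values were seen. It rose from 0.164 ± 0.0901 to 3.92 ± 1.18 CPM (adjusted p = 0.0432), and this call too ended without any 1 of the 6 libraries. These 5 were the edgeR calls of 11657 genes, with 721 at an unadjusted p under 0.05, and DESeq2 called 83. The number was 9, 1, 1, 2 and 0 without control 1, control 2, control 3, AFFN1 1 and AFFN1 3. Groups did not overlap in 9.52% of genes, where chance gives 10% for unpaired libraries and pairs can make it rarer.

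With the block 65 genes were called between AFFN1 and control on day 14, 37 higher and 28 lower, and 263, 25 and 1 without the libraries numbered 1, 2 and 3. Nynrin, the leukotriene receptor gene Cysltr1, Stag3, Pcdhgb6 and Fbln1 then rose by 2.42 to 3.72 on the log2 scale, and Nkg7, a gene of cytotoxic granules, by 2.11. B3gnt3 fell by 3.09, the integrin gene Itgb3 by 2.52, Lif by 2.30 and Cdk5rap1 by 1.95. None of the fixed genes named here with enough reads was called with or without the block, and Hoxa9 was at 0.542 ± 0.198 against 0.978 ± 0.881 CPM (SD, n = 3; adjusted p = 0.902). Of 20 pro-B and pre-B genes none was called (with the block 5 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.33 (adjusted p = 0.000578, and adjusted p = 0.806 with an estimated correlation; 0.272 without AFFN1 3 and 0.402 without control 1). Of 20 Myc and ribosome biogenesis genes none was called (with the block 13 fell adjusted over the list alone), with a median of -0.51 (adjusted p = 3.08e-09, and adjusted p = 0.786 with an estimated correlation). Of 15 p53 target genes none was called, over all genes or adjusted over the list alone, with a median of -0.35 (adjusted p = 0.0114, and adjusted p = 0.786 with an estimated correlation; 0.0567 without AFFN1 2 and 0.0589 without control 2). Control 1 and AFFN1 1 were the libraries with interferon response genes at 59.8 and 65.2 CPM.

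Gldc was called lower in both fusions on day 14, and no other gene was shared. With the block, 25 genes rose and 20 fell in both, where independent lists would share 1.83 and 1.85, and none went opposite ways. Simulations of unchanged groups with the block gave a mean of 0.17 higher and 0.1 lower. A mean of only 1.46 genes for BN1 and 1.21 for AFFN1 was called in them, too few to serve as a baseline for this overlap. The correlation of log2 fold changes was 0.548 (0.5 simulated) and the covariance 0.155 (0.0745 simulated), and with the block 0.56 (0.5) and 0.152 (0.0416). Part of the excess may come from the shared controls.

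Between the fusions on day 14, edgeR called 0 of 11657 genes, with 992 at an unadjusted p under 0.05, and DESeq2 called 90. With the block 21 were called, 8 higher in BN1 and 13 lower, and 124, 5 and 0 without the libraries numbered 1, 2 and 3. Smoc1, Zfp709 and Irak3, a brake on Toll-like receptor signalling, were higher in BN1 by 3.94, 3.77 and 3.68 on the log2 scale, Lynx1 by 1.94 and Ccl9 by 1.57. Fbln1 was lower by 2.51, Ccdc166 by 1.78, the chemokine receptor gene Cxcr5 by 1.22, Cst7 by 1.08 and Cisd1 by 0.95. The fixed genes named here were not called or had too few reads, with or without the block. Groups did not overlap in 16.9% of genes, against 10% by chance for unpaired libraries.

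No member of any list was called over all genes between the fusions on day 14. Genes of Myc and ribosome biogenesis had a median log2 difference of -0.40 between BN1 and AFFN1 (20 tested; with the block 2 fell adjusted over the list alone; adjusted p = 2.71e-05, and adjusted p = 0.622 with an estimated correlation; 0.0537 without AFFN1 1). DNA replication genes had -0.32 (20 tested; 4 fell and 1 rose with the block adjusted over the list alone; adjusted p = 3.72e-05, and adjusted p = 0.622 with an estimated correlation). Targets of KMT2A fusions had 0.16 (15 tested; 2 rose with the block adjusted over the list alone; adjusted p = 0.00225, and adjusted p = 0.191 with an estimated correlation). B-lineage transcription factors had 0.17 (17 tested; 2 rose with the block adjusted over the list alone; adjusted p = 0.0226, and adjusted p = 0.622 with an estimated correlation; 0.172 without AFFN1 1 and 0.135 without BN1 2). The p53 targets had -0.29 (15 tested; 1 fell with the block adjusted over the list alone; adjusted p = 0.0498, and adjusted p = 0.622 with an estimated correlation; 0.206 without AFFN1 3, 0.0623 without BN1 1 and 0.283 without BN1 2). Stromal cell genes had -0.62 (14 tested; 1 fell adjusted over the list alone; adjusted p = 0.00225, and adjusted p = 0.622 with an estimated correlation; 0.151 without BN1 2). Interferon response genes had -3.39 (15 tested; none called adjusted over the list alone; adjusted p = 0.00309, and adjusted p = 0.75 with an estimated correlation), and 0.878 without AFFN1 1, the library with their high median of 65.2 CPM. With the block alone, the immediate early and stress list (adjusted p = 0.0138, against 0.0807 without) and the erythroid and megakaryocyte list (0.00664, against 0.404) also passed, the first higher and the second lower in BN1. With an estimated correlation their adjusted p with the block was 0.666 and 0.32.

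The days were compared in control cells, where the day and the experiment cannot be told apart. A difference in how the reads of the 2 days were counted also stays open. On day 14 control cells expressed Xist, the RNA of the inactive X chromosome, at 395 ± 122 CPM (SD, n = 3) against 0.0949 ± 0.0365 CPM on day 6. The Y-linked genes Eif2s3y, Kdm5d and Uty had 0 reads on day 14 and were at least 1120-, 796- and 536-fold lower. Every day 6 library, fusions included, had at least 1061 reads of Eif2s3y and 480 of Uty. These values point to male donors on day 6 and female donors on day 14. Crip1 was 1570-fold higher on day 14, at 158 ± 2.97 against 0.0882 ± 0.102 CPM (adjusted p = 1.47e-09). Cd2, a lymphocyte adhesion receptor, was at least 210-fold higher, and Gldc, with 1 read on day 6, had a ratio of 1450 (interval 260 to 57500). One of the 2 gene models of Nnt in the table, ENSMUSG00000116207, was at least 1170-fold higher, and Mia3 and Zfp131, with 0 reads on day 14, were at least 1120- and 811-fold lower. These gene models had 0 reads in every library of the lower day, fusions included, so they may reflect the counting rather than the cells. Meis1 fell by 2.58 on the log2 scale (adjusted p = 0.00104), Kit by 0.87 and Brd9 by 0.47, and Pax5 rose by 0.59. Ebf1 rose by 0.68 (adjusted p = 0.0254; 0.128, 0.0773 and 0.0952 without day 14 control 3, day 6 control 1 and day 6 control 2). Hoxa9 rose by 2.15 (adjusted p = 0.0224; 0.218, 0.0747 and 0.0607 without day 14 control 1, day 6 control 2 and day 6 control 3). Flt3, Myc, Aff1 and Il7r were not called, with log2 fold changes of -1.18, 0.90, 0.22 and -0.12, but with the block Flt3 was lower (adjusted p = 1.57e-05) and Myc higher (adjusted p = 0.0215). In a comparison of days the block takes the spread between the numbered sets out of the error, although the days share no set. Calls with the block may therefore rest on too small a spread. In all, edgeR called 5512 of 12567 genes, 2817 higher on day 14 and 2695 lower. With the block, and with the limit just given, it called 6393, 3162 higher and 3231 lower. In 51.1% of genes the groups did not overlap, against 10% by chance.

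Of 17 B-lineage transcription factors 12 were higher on day 14 in control cells and 2 lower, also when adjusted over the list alone (adjusted p = 0.017, and adjusted p = 0.651 with an estimated correlation; 0.0526 without day 6 control 2). Ikzf3 rose 6.18-fold, Irf4 4.61-fold, Spib 3.83-fold and Pou2af1 2.48-fold. Genes of other lineages were called too, though their lists did not pass: of 13 T, NK and innate lymphoid genes 7 were higher and 3 lower (median log2 fold change 1.35, adjusted p = 0.0509), and of 6 erythroid and megakaryocyte genes 3 were higher and none lower (median 1.62, adjusted p = 0.332). Of 16 later B-cell genes 10 were higher and 1 lower, also when adjusted over the list alone (adjusted p = 0.0408, and adjusted p = 0.766 with an estimated correlation; 0.16 without day 14 control 3 and 0.0526 without day 6 control 2). Igkc, the kappa light chain constant gene, was 80.3 ± 85.6 against 0.308 ± 0.131 CPM (SD, n = 3; adjusted p = 0.00122), and H2-Ab1, a class II antigen presentation gene, was at least 8.53-fold higher. Of 13 mitochondrially encoded genes 12 were higher and 1 lower, also when adjusted over the list alone (adjusted p = 4.35e-08, and adjusted p = 0.651 with an estimated correlation). Among them mt-Atp8 rose 18-fold, mt-Cytb 4.55-fold, mt-Nd4 3.85-fold and mt-Nd1 3.59-fold. The lower gene was mt-Nd6, transcribed from the opposite strand to the others, and different counting on the days stays open here too. Mitochondrial genes took 6.7 ± 1.54% of the counts in day 14 control libraries and 2.47 ± 0.177% in those of day 6. Of 5 sex-linked genes 1 was higher and 4 lower, also when adjusted over the list alone (adjusted p = 8.61e-25, and adjusted p = 0.000234 with an estimated correlation), with a median log2 fold change of -12.1 as fitted and -9.64 with the genes at 0 set to their bound. Of 18 interferon response genes none was called without the block and 15 were lower with it (17 adjusted over the list alone). That list had an adjusted p of 0.000392 with the block and 0.154 without, and an adjusted p = 0.723 with the block and an estimated correlation. Without day 14 control 1 and without the block its adjusted p was 0.000253. The list's median was 59.8 CPM in day 14 control 1 and 1.05 and 0.907 CPM in day 14 controls 2 and 3. The block takes this spread out of the error, although it belongs to a comparison of days, so the calls with the block do not allow for it.

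Whether a fusion's difference from control changed between the days was tested in all 18 libraries. The rise of Hoxa9 on day 6 was not seen on day 14. For BN1 its log2 fold change was 5.66 on day 6 and 0.95 on day 14, a change of -4.70 (SE 0.87, adjusted p = 0.00483), and for AFFN1 it was 5.88 and -0.85, a change of -6.72 (SE 0.91, adjusted p = 0.00071). Meis1 did not pass for BN1 (a change of -0.37, adjusted p = 0.899), and for AFFN1 it passed with the block alone (-2.98, adjusted p = 0.0838 without and 0.00518 with the block). Flt3 too passed with the block alone, with adjusted p of 0.0339 for BN1 and 0.00111 for AFFN1 (0.7 and 0.455 without it). The effect of BN1 on Kit rose by 1.48 (adjusted p = 0.00746). For BN1 373 of 12567 genes were called, 242 with a higher and 131 with a lower effect on day 14 (649 with the block, 402 and 247). For AFFN1 183 were called, 91 and 92 (319 with the block, 162 and 157), and 110 without day 6 AFFN1 1 and 117 without day 6 AFFN1 2.

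Of 11 Hoxa genes 5 passed the filter, and 1 of these had a lower effect on day 14 for BN1 (3 adjusted over the list alone; median change -3.08, adjusted p = 0.000602, and adjusted p = 0.507 with an estimated correlation). For AFFN1 it was 3 of 5 (4 adjusted over the list alone; median change -5.02, adjusted p = 1.42e-12, and adjusted p = 0.00895 with an estimated correlation, which was 0.0591 with the block). For BN1 the Myc and ribosome biogenesis list (20 genes, median change -0.59) and the interferon response list (18 genes, median change -4.23) also passed, each with an adjusted p = 0.000602 and none of their members called, over all genes or adjusted over the list alone. With the block 4 interferon response genes were called lower over all genes and 7 adjusted over the list alone, and no Myc and ribosome biogenesis gene. With an estimated correlation the adjusted p was 0.936 for both lists. The interferon list had an adjusted p of 0.678 without day 14 control 1. With the block alone the erythroid and megakaryocyte list passed for BN1 (adjusted p = 0.00797, against 0.0738 without, and adjusted p = 0.252 with the block and an estimated correlation), with 2 of 6 genes lower.

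Few day 6 calls recurred on day 14. Of 722 genes called by more than 2-fold in BN1 on day 6 and tested on day 14, 473 (65.5%) had the same sign on day 14. The median ratio of the day 14 to the day 6 log2 fold change was 0.132 (interquartile range -0.0836 to 0.436). For AFFN1 the median over 589 genes was 0.142 (-0.0802 to 0.423) and 388 (65.9%) had the same sign. The block was also used on both days, although the day 6 numbers did not pair the AFFN1 libraries with the others. With it 146 genes rose and 121 fell in BN1 on both days, and 50 went opposite ways. Independent lists would share 44.7 and 53.7. For AFFN1 15 rose and 9 fell on both days (2.3 and 1.03 for independent lists), and 2 went opposite ways.

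**Figure D4:**
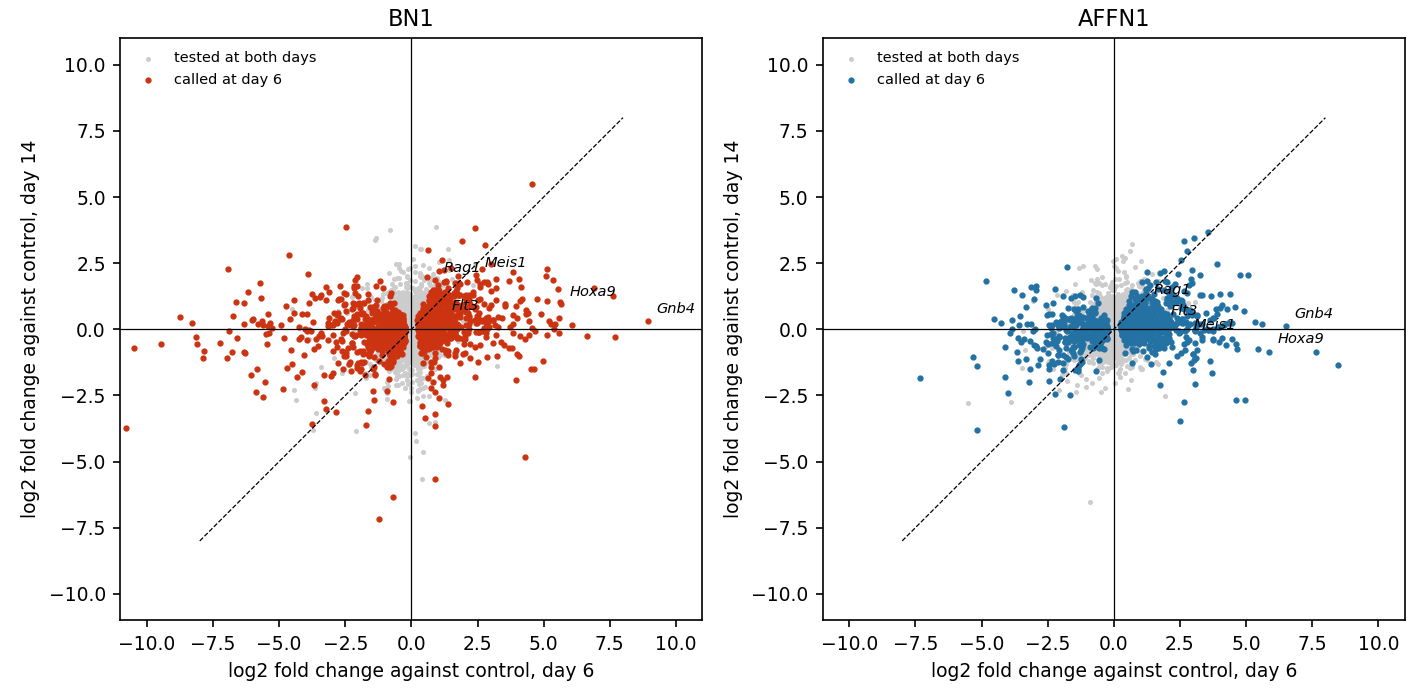
Log2 fold change against control on day 6 (horizontal) and on day 14 (vertical) for each gene tested on both days, for BN1 and for AFFN1. Genes called on day 6 are coloured. Across genes the correlation was 0.237 for BN1 and 0.247 for AFFN1.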

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

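The tests of the interferon pattern, of a deletion, of donor sex and of fewer fusion-carrying cells were chosen only after the results were seen, and the others were chosen before. The results in the first paragraphs stand here because the test of the difference between the effects on day 6 and day 14 called them. A change of effect between the days cannot be told apart from a difference between experiments.

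For BN1 373 genes changed in effect between the days. The larger changes towards a higher effect on day 14 were Zfp267 (9.71, as fitted, with 0 reads in BN1 on day 6), Eci2 (7.87), Dpp4 (7.48), Steap4 (7.44) and Itm2a (7.25). Those towards a lower effect were Gnb4 (-8.63), Lin28b (-6.29), Car2 (-6.15), Tmem132e (-6.05) and Ccnd1 (-5.96), all on the log2 scale. Ccnd1 was lower in BN1 by 1.23 on day 6 (log2 fold change -1.23, edgeR adjusted p = 0.0415) and had a log2 fold change of -7.19 on day 14 (adjusted p = 0.0828). Hoxa9 changed by -4.70 and Kit by 1.48. The Hoxa cluster, the Myc and ribosome biogenesis list and the interferon response list each had an adjusted p of 0.000602. The call of Car2 ended without any 1 of 7 libraries (day 6 control 1, 2 and 3 and BN1 2, day 14 control 3 and BN1 1 and 2), with adjusted p between 0.0503 and 0.0717. In 100 splits of the libraries drawn at random, the real one included, 3 gave as many genes as the real one, the highest of the others 463. That split kept the real groups of day 6 and mixed those of day 14, so a difference on day 6 alone can give such a count, and chance was not excluded for a change of effect. The splits did not use the day 14 pairs.

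For AFFN1 183 genes changed. Those towards a higher effect on day 14 were Snx7 (4.95), Ccdc125 (4.93), Rpgr (4.74), Grb7 (4.58) and Als2cl (4.53). Those towards a lower effect were Gldc (-11.05), Ttc30a1 (-10.2, as fitted, with 0 reads in control on day 6), Crip1 (-8.48), Scd1 (-7.62) and Hoxa9 (-6.72). Of the Hoxa list, which had an adjusted p of 1.42e-12, Hoxa5 changed by -8.08 and Hoxa7 by -4.42. The call of Gldc rested on day 6 AFFN1 3, which held the 12 AFFN1 reads of day 6 (adjusted p = 1 without it). The call of Hoxa7 ended without day 6 AFFN1 1, control 2 or control 3 (0.0537, 0.0592 and 0.0651). That of Ttc30a1 ended without day 6 AFFN1 1, AFFN1 2, control 1 or control 3 or day 14 control 1 (0.0502 to 0.0922). That of Grb7 ended without day 6 AFFN1 1, 2 or 3, day 6 control 3, day 14 AFFN1 3 or day 14 control 3 (0.0527 to 0.0867). That of Als2cl ended without day 6 AFFN1 1, 2 or 3, day 14 AFFN1 3 or any of the day 14 controls (0.0501 to 0.0828). Of 100 random splits, the real one included, 8 gave as many genes as the real one, and chance was not excluded. The highest of the other splits gave 1238, several times the real count, which points to a structure of the samples, and with the replicate block the real count was 319.

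Within a day, the splits of 3 against 3 libraries number 10, too few for a share under 0.05. The real split gave the highest count, or as high a count, in each (1 of 10 for all but BN1 against AFFN1 on day 14, where all 10 gave 0). On day 6 the real and the highest other counts were 2095 and 0 for BN1, 1528 and 355 for AFFN1, and 1349 and 0 between the fusions. On day 14 they were 3 and 0 for BN1 and 5 and 0 for AFFN1, and between days in control 5512 and 0. With the block on day 14, the splits that part all 3 pairs number 4, also too few, and the real and the highest other counts were 1348 and 0, 65 and 0, and 21 and 1, the real one the highest (1 of 4) in each.

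Most day 6 effects were not seen on day 14, and a larger spread between day 14 libraries would leave the fold changes in place and lower the number of calls alone. The median ratio of the day 14 to the day 6 log2 fold change was 0.132 over 722 genes for BN1 and 0.142 over 589 genes for AFFN1, below the bound of 0.5 set for that explanation. This argues against spread as the whole cause, not as a part. The fitted coefficient of variation between libraries of a group was 14.7% on day 6. On day 14 it was 26.2%, and 16.5% with the block, where the BN1 calls went from 3 to 1348. Picking genes by their day 6 calls may itself lower the ratio. Fewer fusion-carrying cells on day 14 would shrink the effects without turning them. With the block 15.8% of the genes called in BN1 on both days (50 genes) went opposite ways, above the 5% set for it. How many unrelated calls would go opposite ways was not computed. In simulation 10.6% of the day 14 calls for BN1 with the block were false. The share therefore cannot decide for or against this explanation. The day 6 numbers did not pair the AFFN1 libraries, which share that fit. With the block on day 14 alone, 34 genes called by more than 2-fold on day 6 were called the opposite way on day 14. The same way went 97, and for the same reasons these counts cannot decide either. For AFFN1 18 such genes were called the same and 1 the opposite way. Open explanations are fewer fusion-carrying cells, a difference between experiments or donors and a change with time in the cells. Each may contribute, and the design cannot part them.

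Interferon response genes were high in 2 of the 3 day 14 libraries numbered 1, control and AFFN1, and not in the BN1 library, which could belong to another set, but without the interferon genes its lowest correlation with the libraries numbered 1 was 0.296, against -0.0374 at most with other numbers (0.295 and -0.0361 with libraries scaled before low counts were removed). Cells of another type in the control and AFFN1 libraries would raise the lists of that type. Of the 5 lists of other cell types tested, 0 had a median log2 ratio above 1 in both. Dendritic cell genes were at 0.79 and 1.61 without the interferon response gene Irf7. Neutrophil and monocyte genes were at 0.219 and 0.0904, though Ly6c2 among them rose by 6.16 and 6.97. The mast cell and basophil list had too few tested genes. Medians of short lists cannot exclude a small share of other cells. With Irf7 the dendritic median was 53.8 CPM in control 1 and 135 CPM in AFFN1 1 against 7.42 to 15.2 CPM in the other 7 libraries. Siglech, Clec9a and Cd209a of that list had 0 reads in both, which argues against dendritic cells that express these genes. A lowering of interferon response genes by BN1 wherever they are expressed is opposed by day 6, where their median log2 fold change in BN1 was 0.48. Several explanations stay open, with 1 library per group. They are a small share of other cells, an interferon response that differed between the cultures or animals of that number, and a BN1 effect on it on day 14 alone.

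With at least 100 reads in each library of the other day, 7 genes had 0 in all 9 libraries of a day (Disp1, Mia3, Jrkl, Zfp131, Eif2s3y and Uty on day 14, the Nnt gene model ENSMUSG00000116207 on day 6), and antisense genes were lower on day 14 (median log2 fold change -0.83 over 329 genes, 27 higher and 124 lower). A deletion spanning the neighbours Disp1 and Mia3 is opposed by Aida and Brox, which lie between them and had at least 733 reads in every day 14 library, while donor sex would account for the Y-linked Eif2s3y and Uty, as for the Xist of day 14, but not for the 5 of the 7 genes that lie on autosomes. A different use of strand in counting stays open: noncoding genes that overlap a stronger gene on the other strand had a median log2 difference of -0.87 (357 genes) and other noncoding genes of -0.44 (525 genes), and this difference of -0.433 lay between the bounds set for and against it. Among the antisense genes, the class in which the fall was seen, the medians were -1.08 with such an overlap (242 genes) and -0.34 without (87 genes). A different gene annotation on each day may also be the cause and was not tested, and besides a deletion and donor sex no biological explanation was tested.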

How the results depend on the processing

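Leaving out the libraries numbered 1 or 3, DESeq2 with the block, the block with a number left out and the overlaps with the block were chosen after seeing the data, and the rest before. The causes of the changes given here were not tested. Scaling mattered least: with size factors by relative log expression the calls for BN1 on day 14 went from 3 to 5 and the overlap of higher genes on day 14 from 0 to 1. With DESeq2 the calls on day 14 were 642 for BN1, 83 for AFFN1 and 90 between the fusions, and the changes of effect between days 599 for BN1 and 338 for AFFN1. Without a filter on low counts they were 17, 25 and 5 on day 14, and 8 lists were called for BN1 on day 6 and 3 for the change of the AFFN1 effect.

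With the replicate block the calls on day 14 were 1348, 65 and 21 and the changes of effect 649 and 319. The overlaps with the block were 25 higher and 20 lower between fusions on day 14, 146 and 121 between days for BN1, and 15 and 9 for AFFN1. Opposite calls between days were 50 for BN1 and 2 for AFFN1. On day 6 the numbers did not pair the libraries of all groups. The 9 same-number correlations ran from -0.322 to 0.349, with 4 over 0.1, and 5 of 18 others were over 0.1, up to 0.398. Control and BN1 libraries of the same number correlated at 0.157, 0.338 and 0.349, so the same-number pairs under 0.1 all held an AFFN1 library. The block on day 6 gave 1801, 1347 and 1233 calls. DESeq2 with the block gave 1802, 284 and 357 on day 14. The block without the libraries numbered 1 gave 594, 263 and 124, without those numbered 2 it gave 143, 25 and 5, and without those numbered 3 it gave 684, 1 and 0. Without a block, leaving out the libraries numbered 1 gave 18 for BN1 and 11 for AFFN1 on day 14, and leaving out those numbered 3 on day 6 gave 3890 and 3873, with 11, 12 and 5 lists called.

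With all 18 libraries in one fit the calls were 1032, 676 and 624 on day 6 and 691, 51 and 76 on day 14. With only the libraries compared in the fit they were 25, 1 and 2 on day 14. With an estimated correlation 0 lists were called in each comparison at camera, besides 1 between days in control and 1 in the change of the AFFN1 effect.

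Leaving out each library in turn gave 1141 to 3495 calls for BN1 on day 6, 739 to 2250 for AFFN1 and 725 to 1047 between them. On day 14 it gave 1 to 5, 0 to 9 and 0 to 0, between days in control 4749 to 5277, and for the changes of effect 267 to 381 for BN1 and 110 to 214 for AFFN1. Lists called ranged from 3 to 8, 4 to 10 and 1 to 4 on day 6, from 8 to 11, 2 to 7 and 4 to 10 on day 14, from 2 to 7 between days, and from 3 to 6 and 1 to 6 for the changes of effect. Where this left 2 libraries in a group, the spread came from all groups of the fit. The list of interferon response genes reversed its direction in 4 of these fits: BN1 on day 14 without control 1 (adjusted p = 0.778), AFFN1 on day 14 without AFFN1 1 (0.00264), between the fusions on day 14 without AFFN1 1 (0.878) and the change of the AFFN1 effect without day 14 control 1 (0.0284). Over all fits with a library left out, the adjusted p of the list ran from 7.38e-05 (without control 3) to 0.778 for BN1 on day 14, from 0.000181 (without control 1) to 0.51 (without control 2) for AFFN1, from 1.26e-05 (without AFFN1 2) to 0.878 between the fusions (Interferon response genes, D14 BN1 vs AFFN1), and from 7.82e-07 (without day 14 AFFN1 1) to 0.972 (without day 14 AFFN1 3) for the change of the AFFN1 effect. Each call of a named gene was refitted without each library, and the refits that lost the call were 11 of 186 for BN1, 33 of 234 for AFFN1 and 20 of 102 between them on day 6, 9 of 18 for BN1 and 16 of 24 for AFFN1 on day 14, 6 of 174 between days, and 7 of 144 and 22 of 144 for the changes of the BN1 and AFFN1 effects. Depth limits the genes near the floor, which stand as bounds or with counting intervals.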

Other observations

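The genes in this part were chosen after their values were seen, and the tests that gave their adjusted p were those planned for all genes. Rag1, whose product cuts DNA in antigen receptor recombination, was higher in both fusions on day 6 too. It was 2080 ± 513 CPM in BN1 and 2530 ± 528 CPM in AFFN1 against 1120 ± 201 CPM in control (SD, n = 3), with edgeR adjusted p of 0.0195 and 0.00675. On day 14 its mean was 625 ± 336 CPM in AFFN1, which was not called (adjusted p = 0.79). In control it was lower on day 14 than on day 6, by 1.52 on the log2 scale (adjusted p = 0.00449). The day and the experiment cannot be told apart there. Igll1, the surrogate light chain gene of pre-B cells, was lower in AFFN1 than in control on day 6, by 0.44 on the log2 scale (log2 fold change -0.44, adjusted p = 0.016). In BN1 it was not called (0.00, adjusted p = 0.984).

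Ly6c2 and Ly6a, surface antigens induced by interferon among other signals, moved with the libraries that were high in interferon response genes on day 14. Ly6c2 was 144 CPM in control 1 and 239 CPM in AFFN1 1 and between 1.21 and 2.89 CPM in the other 7 libraries of that day. Ly6a was 1080 and 1170 CPM in those libraries and between 25.1 and 182 CPM in the others. On day 6 Ly6c2 was higher in BN1 as well as in AFFN1, at 153 ± 70.2 against 7.77 ± 1.79 CPM (SD, n = 3; log2 fold change 4.29, adjusted p = 0.000257), while Ly6a was called higher in AFFN1 (log2 fold change 0.62, adjusted p = 0.00196) and not in BN1 (-0.01, adjusted p = 0.953).

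Gldc, the gene called lower in both fusions on day 14, was near 0 in all day 6 libraries, with 0, 1 and 0 reads in control, 0, 0 and 2 in BN1 and 0, 0 and 12 in AFFN1. On day 14 control had 573, 261 and 473 reads, BN1 12, 2 and 12 and AFFN1 2, 2 and 1. The mitochondrial gene mt-Nd6, transcribed from the opposite strand to the other 12 of its list, was 12.7 to 35 CPM in the day 6 libraries and 0.913 to 2.42 CPM in those of day 14, while the other 12 were higher on day 14 in control.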
